A study of Mus musculus with 2 samples.

How the data were processed

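Total RNA of gastrocnemius from male B6CASTF1/J mice aged 10 days was sequenced as long reads in 2 libraries from separate animals, with 2 micrograms of RNA each, per the labels. The deposited values are counts: for each library the authors list raw reads per transcript model, and only models with 1 or more read, with no normalization. Per the deposited descriptions, reads were aligned to the mm10 genome and transcript models were built against GENCODE M21, and the annotation files carry TALON attributes. The aligner and the versions of the tools are not given in the sources used here. The labels cite version 3.1 of the pipeline document for replicate 1 and version 3.0 for replicate 2, so document version and animal cannot be told apart. The deposited transcript annotations gave the exons, the class of each model and the gene it belongs to.

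Both libraries form 1 group, so the comparison made was replicate 1 with replicate 2, which compares those libraries and not conditions. Choices of tests, thresholds, gene lists and alternatives were made before the data were examined, except where a choice is said to follow the data. Gene counts were sums of reads over all transcript models of a gene, and CPM was reads per 1000000.00 mouse reads with spike-ins left out. Genes with 20 or more reads over both libraries were tested by an exact two-sided conditional binomial test with the Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05 and a 2-fold difference. Transcript shares were tested by Fisher's exact test in genes with 20 or more reads in each library, with calls at a difference of 10 points. Unannotated models were matched between libraries by their intron chain. Shares have 95% Wilson intervals and paralogue shares Clopper-Pearson intervals. The correlation across genes used log2(CPM + 1). List medians were compared with 10000 random lists of the same size. Exon inclusion, measured after the data were seen, was the share of reads with introns on both sides of an exon that contain it, and panel exons included in 5% to 95% of reads were counted as variable. The floor was 3 reads per library.

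Genes were named by a fixed rule. It took the sarcomeric heavy chains, up to 6 members of each other list at 10 CPM or more (cell type and sex-label lists at any level), the 20 genes of highest mean CPM, and the 10 largest called folds in each direction. It also took up to 15 genes of the isoform panel whose second transcript had a mean share of 10% or more, the 10 largest called transcript share differences, the 10 most abundant unannotated spliced transcripts found in both libraries, and the 5 unannotated genes with the most reads in both. Some items that this rule takes are not reported here.

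Tests were run in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, figures were drawn with matplotlib 3.10.9, and dispersion and size factors came from edgeR 4.0.16 and DESeq2 1.42.0 in R 4.3.3. Relative to all reads, edgeR TMM shifted the log2 ratio of the libraries by -0.01 and DESeq2 size factors by -0.01. The gene test was tested on simulated data with counting noise, where the adjusted p passed in 50 of 50 genes changed 8-fold, 42 of 50 changed 4-fold, 22 of 50 changed 2-fold and 12 of 50 changed 1.5-fold. With the 2-fold limit as well, 13 of the 50 genes changed 2-fold were called, and 2 of 7329 unchanged genes were. The transcript share test recovered 48 of 200 shifts of 20 points and called 1 of 2800 unchanged transcripts.

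Alternatives tried for the gene calls were TMM and DESeq2 scaling, a library size without mitochondrial genes, read minima of 5 and 100 and none, annotated-transcript reads only, leaving out the genomic class, any fold, and thinning the deeper library. For correlations, dispersion, classes, transcript shares, lists, paralogues and length bins the pseudocount, the read minimum, the denominator and the genes or libraries included were changed in turn. Added after the data were seen were a null share fitted per transcript length bin, for gene calls and paralogue shares, and transcript classes recomputed from splice sites against GENCODE M21. No genome sequence was analysed, so reads primed inside a transcript were not checked. Spike-ins were the ERCC RNAs, and the SIRV set that the labels also name had 0 entries in either library.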

Results

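Long-read sequencing of total RNA was measured in gastrocnemius, a fast-twitch calf muscle, of male mice aged 10 days of the F1 hybrid strain B6CASTF1/J. The series held 1 group with 2 biological replicates, each from its own animal per the labels, and no treatment or control. Replicate 1 held 1172413 reads and replicate 2 held 957529 reads. Of these, 1145490 and 941841 reads were assigned to mouse transcripts and the rest to ERCC spike-in RNA. Reads assigned to annotated genes made up 98.3% and 98.1% of mouse reads, over 14452 and 13740 genes. Genes with 20 or more reads numbered 5688 in replicate 1 and 4899 in replicate 2. Gene levels are given as reads per 1000000.00 mouse reads (CPM), as mean ± SD over the 2 libraries (n = 2) unless a library is named. A count of 0 allowed up to 2.62 CPM in replicate 1 and 3.19 CPM in replicate 2, from a limit of 3 reads. Intervals are 95% Wilson intervals unless Clopper-Pearson is named, and intervals and floors cover counting error only. The tables do not show reads left out before counting, so levels and ranks are those of assigned reads.

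Contractile, calcium-pump and energy genes had the highest levels. Acta1, the skeletal muscle actin, had the highest level at 85092 ± 9445 CPM. Atp2a1, the calcium pump of the fast-fibre sarcoplasmic reticulum, followed at 72982 ± 13167 CPM, and Ckm, the muscle creatine kinase, at 55115 ± 7558 CPM. Among the 20 genes of highest mean level, 8 further genes of the sarcomere were found. These were tropomyosin Tpm1 (19418 ± 3438 CPM), fast troponin C Tnnc2 (18053 ± 4529.6 CPM), the heavy chains Myh4 (16129.6 ± 10265 CPM) and Myh1 (5886 ± 2646 CPM), the light chains Mylpf (12729 ± 540.1 CPM) and Myl1 (11214 ± 1813 CPM), Mybpc2 (4849 ± 1564 CPM) and Actn3 (5449.9 ± 348 CPM). Casq1, which binds calcium in the sarcoplasmic reticulum, lay at 8443 ± 446 CPM. The energy genes among the 20 were the ADP/ATP carrier Slc25a4 (9825 ± 2126 CPM), enolase Eno3 (9702 ± 1064 CPM), aldolase Aldoa (8468 ± 361 CPM), lactate dehydrogenase Ldha (7710.4 ± 931 CPM), adenylate kinase Ak1 (5596 ± 712 CPM) and pyruvate kinase Pkm (4628 ± 254 CPM). The fibrillar collagens Col3a1 (8099 ± 2853 CPM) and Col1a1 (6082 ± 2638 CPM) completed the 20. The 10 highest genes took 31.2% of mouse reads in replicate 1 and 31.0% in replicate 2.

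Adult fast myosin heavy chains made up most sarcomeric heavy-chain reads at day 10, and the embryonic and perinatal forms remained as a small share. Myh4, the IIB chain (chromosome 11, 67238029 to 67260446, mm10), held 64.8% ± 5.44 of sarcomeric heavy-chain reads (SD, n = 2), and Myh1, the IIX chain, held 25.2% ± 3.41. The perinatal chain Myh8 held 3.54% ± 0.108, the slow chain Myh7 3.11% ± 1.25, the IIA chain Myh2 3.01% ± 0.885 and the embryonic chain Myh3 0.360% ± 0.00608. Myh3 and Myh8 together held 3.97% (3.78 to 4.17) in replicate 1 and 3.83% (3.51 to 4.16) in replicate 2 (Clopper-Pearson intervals). The share of Myh4 was 68.6% (68.2 to 69.1) in replicate 1 and 60.9% (60.1 to 61.8) in replicate 2, so the libraries differed by more than counting error. Myh6, the atrial chain, had 6 reads in replicate 1 and 0 in replicate 2, Myh7b had 1 read in each library, and Myh13 had 0 and 1. Myh15 was not listed in either library. Counted over annotated transcripts alone, the order of Myh4 and Myh1 turned, with 46.8% for Myh1 and 39.7% for Myh4, and the shares of Myh7 and Myh3 were 6.93% and 0.593%. Such transcripts held 21.1% of Myh4 reads and 63.4% of Myh1 reads (means of 2).

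**Figure D1:**
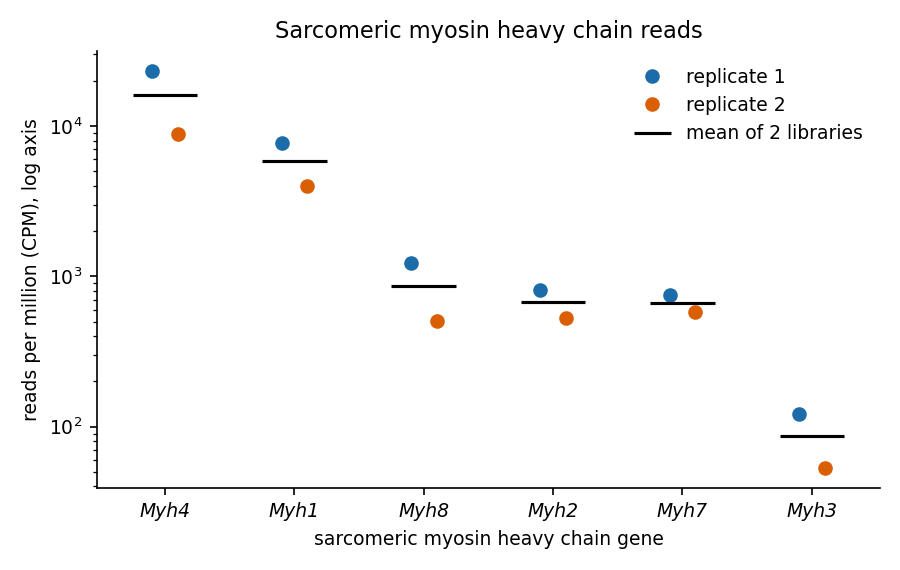
Level in CPM (log axis) of the 6 sarcomeric myosin heavy chain genes with 20 or more reads in each library, with 1 point per library and a bar at the mean of 2. Myh4 lies at 23388 CPM in replicate 1 and 8871 CPM in replicate 2, above the other 5 genes in both when all transcript models are counted.

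Counted over all transcript models, the member taken as fast or adult outnumbered its counterpart in each pair of paralogues compared. Atp2a1 held 99.8% ± 0.00890 of the reads of the pair with Atp2a2, the slow and cardiac pump (SD, n = 2), and 4.22% when only annotated transcripts were counted, since the main Atp2a1 models are absent from the annotation. The fast share was 98.7% ± 0.252 for troponin C, 92.7% ± 3.45 for troponin I and 79.5% ± 2.09 for troponin T. The troponin T share rested on 880 and 989 Tnnt3 reads, of which 0.341% and 0% were on annotated transcripts. Of Tnnt1 reads, 71.6% (mean of 2) lay in 1 incomplete model of 3 exons, so this share is less certain. Mylpf held 99.6% ± 0.0190 of its pair with Myl2, Myl1 98.6% ± 0.176 of its pair with Myl3, and Casq1 95.9% ± 0.187 of its pair with Casq2. Mybpc2, fast myosin-binding protein C, held 76.9% ± 3.99 against Mybpc1. Over annotated transcripts alone it held 94.6%, as such transcripts held 14.2% and 17.0% of Mybpc1 reads in replicates 1 and 2. So counted, the troponin I share was 100% in place of 92.7%. Actn3, the fast alpha-actinin, held 65.1% ± 2.77 against Actn2, the lowest share of the pairs. Myoz1 held 93.1% ± 1.97, Tpm1 97.5% ± 1.27, Ldha 98.4% ± 0.208 against Ldhb, and Eno3 91.6% ± 1.79 against Eno1. Among adult and developmental pairs, Acta1 held 98.2% ± 0.673 against cardiac actin Actc1, Myl1 99.7% ± 0.0907 against Myl4, and Tnnt3 99.6% ± 0.417 against Tnnt2. Chrne, the adult acetylcholine receptor subunit, held 84.6% (71.9 to 93.1) in replicate 1 and 81.6% (65.7 to 92.3) in replicate 2 against the fetal subunit Chrng (Clopper-Pearson). Both libraries belong to 1 group, so these shares are described without a test between groups. Each is a share of reads between 2 genes, and none was taken as a measure of fast and slow fibres. Eno1 was not among the slow-fibre genes.

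The fixed lists of muscle genes lay high among expressed genes. The 15 genes of the fast-fibre list summed to 170839 ± 27492 CPM and the 15 genes of the slow-fibre list to 7819 ± 673 CPM. Actn2 (2923 ± 169.6 CPM), Mybpc1 (1409 ± 144 CPM) and the fatty-acid carrier Fabp3 (693 ± 266 CPM) were highest among the slow list. Neither sum was taken as a measure of fibre types. The 10 sarcomeric heavy chains summed to 24316 ± 13802 CPM (34076 in replicate 1 and 14557 in replicate 2), the myosin light chains to 24474 ± 2445 CPM and the non-muscle and smooth muscle heavy chains to 70.6 ± 24.8 CPM. The glycolysis and glycogen list summed to 99077 ± 8152 CPM. Most of this came from Ckm (55115 ± 7558 CPM), a listed member that is a creatine kinase and not a gene of glycolysis or glycogen. Nuclear genes of oxidative phosphorylation summed to 30270.5 ± 4463 CPM, with Atp5b (4421 ± 354 CPM) and Atp5a1 (3143 ± 138 CPM), subunits of ATP synthase, after Slc25a4. Calcium-handling genes summed to 86275 ± 13569 CPM and included triadin Trdn (921 ± 235 CPM) and the calcium channel subunits Cacna1s (636 and 241 CPM in replicates 1 and 2) and Cacnb1 (423 ± 17.5 CPM). The large structural genes summed to 2844 ± 854 CPM, with the M-band proteins Myom2 (792 ± 337 CPM) and Myom1 (592 ± 199 CPM) highest and Ttn, titin, at 277 and 127 CPM in replicates 1 and 2. Neuromuscular junction genes summed to 506 ± 70.4 CPM, led by the receptor subunit Chrna1 (108 ± 5.37 CPM) and acetylcholinesterase Ache (130.1 and 68.0 CPM in replicates 1 and 2). Over annotated transcripts alone, the sums were 14735 CPM for calcium handling, 105418 CPM for the fast list, 12026 CPM for sarcomeric and 30.5 CPM for other heavy chains, and 1299.9 CPM for the large structural genes, each lower by more than 1.5 times. The median percentile among expressed genes was 99.9 for the fast list, 97.1 for the slow list, 98.0 for calcium handling and 99.7 for glycolysis, and 0% of 10000 random lists of the same size reached any of these 4 medians. The percentile was 78.8 for the junction list, which 0.830% of random lists reached. These lists were drawn up for muscle, so high ranks, here and for the developmental and myogenic lists, are a description and not a test. The 4 medians are also not separate, since the fast and calcium-handling lists share members such as Atp2a1 and Casq1.

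Developmental and myogenic genes were still read at day 10. The developmental list summed to 6956 ± 1513 CPM, led by the imprinted RNA H19 at 3250.1 ± 445 CPM, cardiac actin Actc1 at 1557 ± 418 CPM and Myh8 at 1233 and 504 CPM in replicates 1 and 2. Dlk1, an imprinted inhibitor of adipocyte differentiation, lay at 382 ± 46.2 CPM, and Myog, the transcription factor myogenin, at 326 ± 59.1 CPM. The myogenic list summed to 4526 ± 517 CPM, with the intermediate filament desmin (Des) at 3501 ± 533 CPM, Mef2c at 242 ± 39.1 CPM and Myf6 at 137 ± 23.7 CPM. The developmental list had a median percentile of 90.8, which 0.010% of random lists reached, and the myogenic list 84.3, which 0.0700% reached.

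Markers of other cell types were present beside the muscle genes. Matrix and fibroblast genes summed to 18991 ± 5866 CPM, with Sparc at 1604 ± 9.27 CPM, Col1a2 at 982 ± 82.6 CPM and decorin (Dcn) at 561 ± 70.0 CPM after Col3a1 and Col1a1. The adipocyte list summed to 3687 ± 1298 CPM, of which Car3, a carbonic anhydrase that muscle fibres also express, gave 3351 ± 1280.2 CPM, while Adipoq, the fat-cell hormone adiponectin, lay at 4.93 ± 2.04 CPM. Schwann cell and nerve genes summed to 1567 ± 310.3 CPM, with the myelin genes Pmp22 (693 ± 125 CPM) and Mbp (424 ± 40.5 CPM). Endothelial and mural genes summed to 1211 ± 45.2 CPM, tendon genes to 654 ± 6.59 CPM with Fmod (213 ± 6.56 CPM) and Tnmd (147 ± 39.9 CPM) highest, and immune genes to 171 ± 10.3 CPM with Lyz2 at 33.2 ± 2.55 CPM. Red-cell genes summed to 409 CPM in replicate 1 and 853 CPM in replicate 2, and the alpha-globin gene Hba-a1 was 2.45-fold higher in replicate 2. The share of random lists that reached the list's median percentile was 0% for matrix, 0.640% for red-cell, 0.70% for endothelial, 2.15% for tendon, 5.6% for Schwann cell, 15.8% for immune and 22.7% for adipocyte genes. Skin keratinocyte genes were represented by Krt10 alone, at 4.36 and 9.56 CPM in replicates 1 and 2, close to the floor, and at a mean of 0.708 CPM over annotated transcripts. Of the sex-label genes, the Y-linked genes Ddx3y (57.6 ± 22.2 CPM), Eif2s3y (50.2 ± 1.89 CPM), Uty (13.5 ± 1.87 CPM) and Kdm5d (2.90 ± 0.400 CPM) were listed in both libraries, and Xist in neither, in mice labelled male.

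Atp2a1, Tnnt3, Bin1 and Mef2c gave reads both with and without an alternative exon in each library. Few exon choices were called different between the libraries. Atp2a1 gave both known forms of its end. Its 42-nt exon at chromosome 7, 126446545 to 126446586 (mm10), whose skipping gives the neonatal pump SERCA1b, was included in 79.9% (79.7 to 80.2) of spanning reads in replicate 1 and 79.8% (79.5 to 80.1) in replicate 2. Tnnt3, fast troponin T, used 2 alternative exons of 41 nt. The exon at chromosome 7, 142513665 to 142513705, was included in 66.7% (63.3 to 69.9) and 56.4% (53.2 to 59.5) of reads, and the exon at 142514326 to 142514366 in 34.2% (31.0 to 37.6) and 43.7% (40.6 to 46.9). Myl1, which encodes the fast essential light chains from alternative promoters, gave 56.1% ± 4.16 of its reads to Myl1-202 and 29.3% ± 5.61 to Myl1-201 (SD, n = 2). The 45-nt exon of Gnas, the stimulatory G-protein subunit gene, was included in 69.1% and 67.5% of reads, and the 72-nt exon of Bin1, a gene of T-tubule shape, in 69.4% and 69.5%. Mef2c, a muscle transcription factor, included its 144-nt exon in 54.6% and 53.8% and its neighbouring 138-nt exon in 44.6% and 40.6%. The 76-nt exons of Tpm3 at chromosome 3, 90088401 and 90089048, were included in 16.5% ± 1.99 and 83.5% ± 1.99. Of 769 internal exons measured in the panel, 85 in 36 genes were included in 5% to 95% of reads. The libraries differed by 10 points or more at an adjusted Fisher exact p under 0.05 at 1 of these, the first Tnnt3 exon (adjusted p = 0.00333), while the other Tnnt3 exon and the Myl1 exons of 28 and 25 nt differed by less than 10 points at adjusted exact p = 0.0101, 4.26e-30 and 1.12e-30. The largest difference, 19.8 points at the Neb exon at chromosome 2, 52150537, was not called. That exon was included in 62.6% of 107 spanning reads in replicate 1 and 42.9% of 49 in replicate 2. Exons with few spanning reads can thus differ widely without a call. Exon inclusion was chosen as a measure, and this Neb exon was named, after the data were seen.

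**Figure D2:**
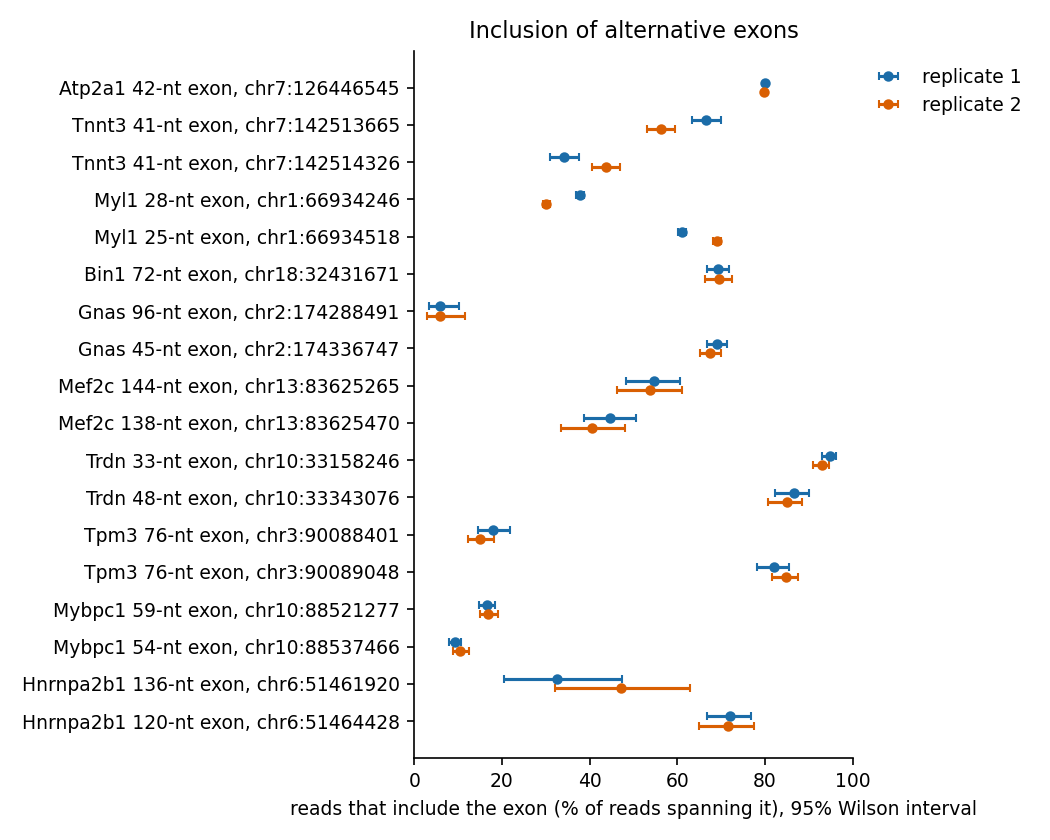
Inclusion of alternative exons, as the percent of reads spanning the exon that contain it, with 95% Wilson intervals, for up to 2 variable exons per gene with the most spanning reads, with 1 point per library. The Atp2a1 exon of 42 nt lies near 80% in both libraries (79.9% and 79.8%), and the Tnnt3 exon at 142513665 lies at 66.7% and 56.4%.

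Over the isoform panel, 53 genes had 20 or more reads in each library. Eno3 reads were divided among Eno3-201 at 51.2% ± 0.415, Eno3-202 at 28.4% ± 0.0440 and Eno3-206 at 9.10% ± 1.29. Aldoa gave 53.8% ± 6.33 to an unannotated combination of its annotated splice sites and 37.9% ± 6.48 to Aldoa-201. Gnas-208 held 53.3% ± 1.23 of Gnas reads and Gnas-207 19.9% ± 0.309. Tpm3-205 held 75.7% ± 0.326 of Tpm3 reads and Tpm3-201 13.7% ± 1.59. Fhl1-204 held 54.9% ± 1.61 of the reads of Fhl1, a LIM-domain gene, and an unannotated model 25.1% ± 1.24. Mybpc1, slow myosin-binding protein C, gave 41.2% ± 2.95 to an unannotated 31-exon model and 15.5% ± 1.88 to Mybpc1-202. Bin1 gave 60.7% ± 2.14 and 26.0% ± 0.696 to unannotated models of 15 and 14 exons. Tnnt3 was spread over many models, the first at 14.1% ± 2.29 and the second at 12.3% ± 1.71. The main models of Trdn (31.8% ± 7.38) and Ryr1, the calcium release channel (27.5% ± 5.93), were incomplete matches. Hnrnpa2b1-204 held 36.4% ± 2.28 of reads of a splicing-factor gene, Synpo2l-202 31.8% ± 2.69 of Synpo2l reads and Mef2c-228 14.3% ± 6.27 of Mef2c reads. As shares of annotated transcripts alone, values moved by more than 1.5 times for Bin1-206 (55.6% in place of 1.91%), Mybpc1-202 (99.3%), Aldoa-201 (95.1%), Fhl1-204 (94.4%), Hnrnpa2b1-204 (65.1%), Synpo2l-202 (58.6%) and Mef2c-228 (44.9%). With only incomplete and genomic reads left out, Hnrnpa2b1-204 held 58.7% and Synpo2l-202 50.6%.

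Most reads matched annotated transcripts in full. Annotated transcripts held 72.9% ± 2.87 of mouse reads (SD, n = 2), incomplete matches 8.09% ± 0.842, and spliced transcripts absent from the annotation 15.4% ± 2.10. Of the last, the deposited classes gave 9.00% ± 4.40 to combinations of annotated splice sites (NIC) and 6.38% ± 2.30 to transcripts with an unannotated splice site (NNC). Genomic reads made up 1.86% ± 0.0591, antisense reads 1.55% ± 0.132 and intergenic reads 0.210% ± 0.00392. The NIC share was 12.1% in replicate 1 and 5.89% in replicate 2, and the NNC share 4.75% and 8.01%. Recomputed from splice sites against GENCODE M21, a check chosen after the data were seen, the NIC shares were 4.28% and 3.97% and the NNC shares 12.6% and 9.93%. The libraries differed in the incomplete share by a two-sided Fisher exact test of reads (adjusted p = 7.70e-216, 8.68% and 7.49%) and a difference in the intergenic share was not detectable at this depth (adjusted exact p = 0.387). A test on the reads of 2 libraries compares those libraries, with no replicate of either.

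**Figure D3:**
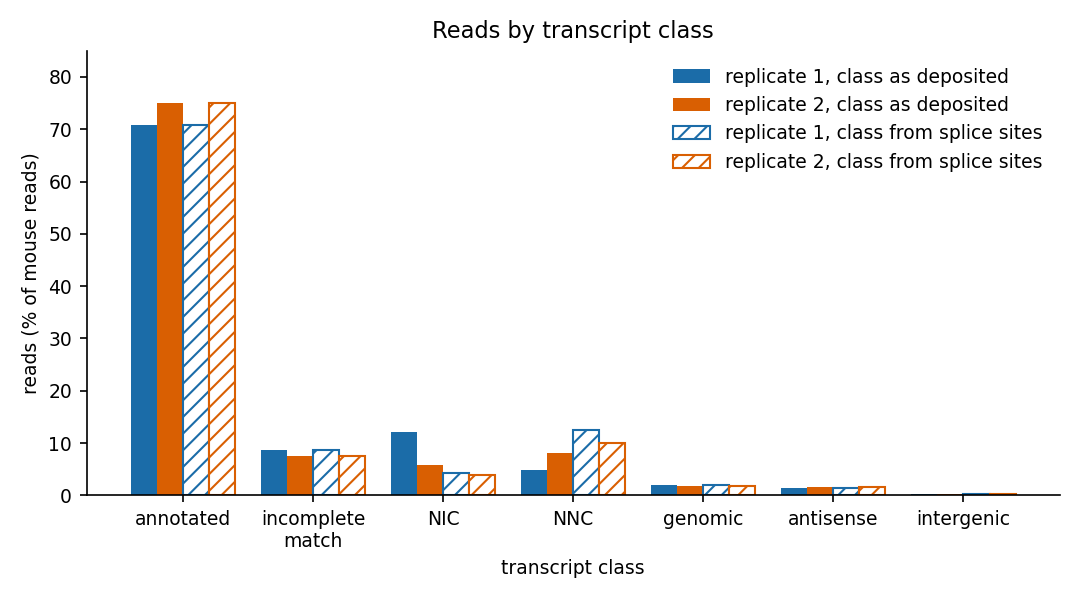
Percent of mouse reads in each transcript class, per library, with the class as deposited (filled) and as recomputed from splice sites (hatched), where NIC and NNC are the spliced classes absent from the annotation. The deposited NIC share is 12.1% in replicate 1 and 5.89% in replicate 2, and the recomputed one 4.28% and 3.97%.

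Atp2a1 carried more unannotated spliced reads than any other gene. An Atp2a1 model of 22 exons and 3485 nt held 53808 ± 9784 CPM, 73.7% ± 0.106 of the gene's reads, and a 21-exon model shorter by the 42-nt exon held 13338 ± 2361 CPM, 18.3% ± 0.0633. Both carried 1 intron absent from GENCODE M21, at chromosome 7, 126462188 to 126462778. A 40-exon Myh4 model held 34.8% of Myh4 reads in replicate 1 and 19.7% in replicate 2. Unannotated combinations of annotated sites held 95.9% ± 0.792 of reads of Oaz1, an inhibitor of polyamine synthesis, 87.3% ± 1.33 of Eno1, 63.7% ± 3.68 of Srl, a sarcoplasmic reticulum gene, and 47.8% ± 0.492 of Ndrg2. Acta1 had an 8-exon unannotated model with 0.729% ± 0.0107 of its reads. The same intron chain was found in the other library for 2024 of 2129 models with 5 or more reads in replicate 1 (95.1%, 94.1 to 95.9). The count was 1605 of 1628 in replicate 2 (98.6%, 97.9 to 99.1). These counts ask for 1 read in the other library, and with 5 or more reads asked of both the shares were 59.0% and 78.1%. For annotated multi-exon transcripts, with 1 read in the other library, they were 98.6% and 99.8%.

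Replicate 1 and replicate 2 were compared gene by gene, and myosin heavy chains, matrix genes and other genes with long transcripts were among those higher in replicate 1, and 2 globin genes among those higher in replicate 2 before a correction for length. Of 7516 genes with 20 or more reads, 207 differed at least 2-fold at an adjusted p under 0.05 (exact conditional binomial test, two-sided), 144 higher in replicate 1 and 63 higher in replicate 2. With reads of annotated transcripts alone 134 were higher in replicate 1 and 36 in replicate 2, at a minimum of 100 reads 41 and 18, and at any fold 336 and 349. Myh4 (IIB, 2.64-fold), Myh8 (perinatal, 2.44-fold) and Myh3 (embryonic, 2.29-fold) were higher in replicate 1, as were the calcium channel subunit Cacna1s (2.64-fold), titin (2.17-fold) and the imprinted RNA Meg3 (2.55-fold). The globin genes Hba-a1 (2.45-fold) and Hbb-bt (2.54-fold) were higher in replicate 2. Of the called genes with main transcripts of 4 to 6 kb, 45 were higher in replicate 1 and 2 in replicate 2, and of those of 6 kb or longer 48 and 0. The median log2 ratio of replicate 1 over replicate 2 was -0.31 for genes with main transcripts under 1 kb and 0.46 for those of 6 kb or longer. With the null share fitted per transcript length bin, chosen after the data were seen, 121 genes were called, 65 and 56 by direction, and 87 were shared with the 207. The log2 ratio was 1.40 for Myh4 before that correction and 0.94 after it, and after it 0.94 for Cacna1s, 0.85 for titin, 0.83 for Myh8 and 0.74 for Myh3, so these calls ended under the 2-fold limit. The globin calls also ended, Hba-a1 under 2-fold (-0.99) and Hbb-bt on the adjusted exact p (0.0662). Meg3 stayed called at a corrected log2 ratio of 1.44.

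**Figure D4:**
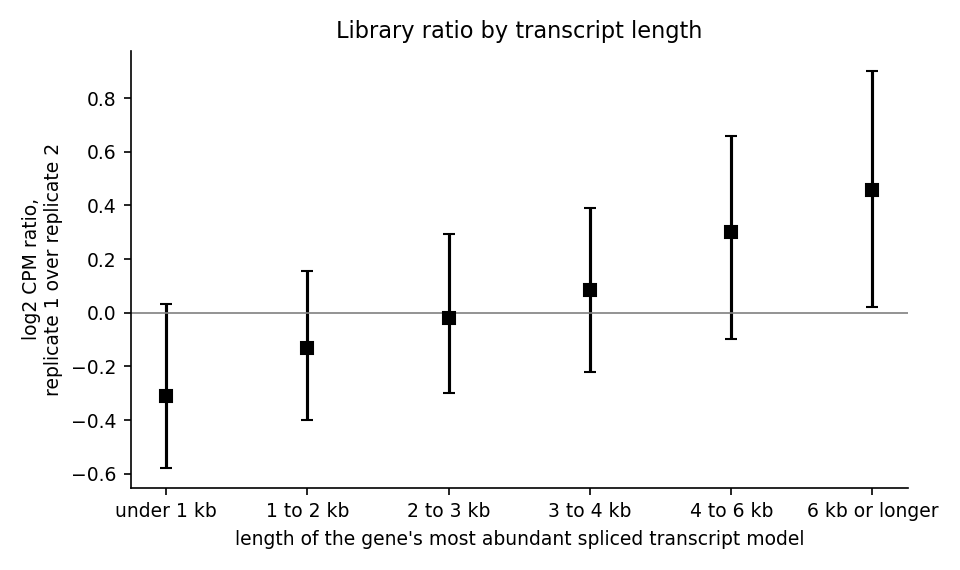
Median log2 ratio of CPM, replicate 1 over replicate 2, of genes in bins of the length of their most abundant spliced transcript model, with bars from the first to the third quartile. The median is -0.31 for the 668 genes under 1 kb and 0.46 for the 504 genes of 6 kb or longer.

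By list, 3 of 6 tested sarcomeric heavy chains were higher in replicate 1, and 3 passed when adjusted over the list alone. That adjustment reuses the same p-values over fewer genes, so here and below it is not a second test. Among the 18 calcium-handling genes, Cacna1s and Jph2 (2.77-fold) were higher in replicate 1 and sarcolipin, Sln (2.16-fold), in replicate 2, and 3 passed adjusted over the list alone. Among 19 matrix genes, Col5a1 (2.14-fold) and Fn1, fibronectin (2.85-fold), were higher in replicate 1, and 2 passed adjusted over the list alone. Of 5 red-cell genes, 2 were higher in replicate 2, and 2 passed adjusted over the list alone. Of 11 developmental genes, 3 were higher in replicate 1 and 4 were called adjusted over the list alone. Single genes of other lists higher in replicate 1 were Prx, a gene of myelinating Schwann cells (3.79-fold), Scd1, a fatty acid desaturase (4.44-fold), and Myh11, the smooth muscle heavy chain (3.29-fold). None of the 18 genes of the glycolysis list, which holds Ckm, was called, at 2-fold, in either direction. The same held for the 20 oxidative phosphorylation genes and the 14 tested genes of the slow-fibre list. With the length correction Jph2, Fn1 and Prx were still called, at log2 ratios of 1.28, 1.06 and 1.65. The calls of Sln, Hba-a1 and Col5a1 ended under 2-fold, at -0.94, -0.99 and 0.64, and those of Hbb-bt, Scd1 and Myh11 on the adjusted exact p (0.0662, 0.0502 and 0.239), at log2 ratios of -1.04, 1.88 and 1.26. Called with that correction alone were Ache (1.02) and the thin-filament gene Neb (1.06), higher in replicate 1, and Ddx3y (-1.08), higher in replicate 2. The most abundant Neb model was an incomplete one of 3 exons and 1045 nt, with 5.59% of Neb reads (mean of 2). A length bin set by such a model need not be that of the whole transcript, so nothing is concluded from the Neb call. Jph2, Sln, Col5a1, Fn1 and Neb were named after their values were seen.

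Dagla and Malat1 had some of the largest folds in replicate 1, and Nmrk2 and Slc25a25 in replicate 2, most of the largest folds resting on few reads. Higher in replicate 1 were Dagla, a diacylglycerol lipase, with 23 and 1 reads (18.9-fold, 3.07 to 779, Clopper-Pearson interval), the pseudogene AC169509.1 (8.63-fold, 2.11 to 75.9), the centrosomal gene Nin (8.22-fold, 2.00 to 72.6) and Xxylt1 (6.30-fold, 1.90 to 32.8). The nuclear RNA Malat1 had 33.2 and 5.31 CPM (6.25-fold, 2.46 to 20.3), and Tbc1d1, a regulator of glucose transport, 5.61-fold, 2.96 to 11.7. Gripap1, Shisal1, Gmppb and Dip2b ranged from 5.21-fold to 5.76-fold. With the length correction the calls of Nin, Shisal1 and Dip2b ended (adjusted exact p 0.0800, 0.0620 and 0.193), at log2 ratios of 3.04 before and 2.58 after for Nin, 2.47 and 2.02 for Shisal1, and 2.38 and 1.93 for Dip2b. Higher in replicate 2 were the pseudogene Gm6563 (15.8-fold, 3.96 to 137), Klhl10 (11.6-fold, 2.79 to 102), and Nmrk2, a nicotinamide riboside kinase of muscle (7.54-fold, 2.91 to 24.8). The pseudogene Gm6829 had 0 reads in replicate 1 and 23 in replicate 2, at least 9.32-fold higher against the floor of replicate 1 with the reads of replicate 2 taken as counted (Clopper-Pearson lower limit 6.99-fold). Slc25a25, a mitochondrial carrier, had the most reads of these genes, at 47.1 and 259 CPM (5.50-fold, 4.08 to 7.52). Lrrc2 was 5.91-fold higher in replicate 2, and Itpkc, 9330159F19Rik and Amot were each 5.17-fold higher.

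Across genes, which are not independent replicates, the libraries had a Pearson r of 0.937 and a Spearman rho of 0.926 over 15631 genes, and the biological coefficient of variation was 0.180 (edgeR). In simulated libraries with this spread, estimated from the same 2 libraries, 204 of the 7273 genes left unchanged were called (2.80%), beside 207 of 7516 (2.75%) in the data, and since the spread came from the same libraries this does not test the count.

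Few annotated transcripts were called at a different share of their gene in the 2 libraries, and the test misses many such shifts. In simulation with counting noise it recovered 48 of 200 shifts of 20 points, so a low count does not show equal shares. Of 9034 transcripts in 4489 genes, 21 in 19 genes differed by 10 points or more at an adjusted p under 0.05 (Fisher exact test, two-sided). Rcan1, a calcineurin regulator, shifted between 2 transcripts: Rcan1-201 held 51.8% (44.2 to 59.3) of its gene's reads in replicate 1 and 79.6% (74.7 to 83.6) in replicate 2, and Rcan1-202 42.1% and 15.3%. Smyd1, a muscle methyltransferase, gave 49.1% and 23.8% to Smyd1-202 and 32.1% and 56.6% to Smyd1-201. The largest difference was in Txnl4a, where Txnl4a-204 held 45.2% and 92.9%. Flot1-201 held 91.2% and 52.6%, and Rpl39-201, of a ribosomal protein, 85.1% and 56.2%. Col4a2-201, of a basement membrane collagen, held 41.0% and 19.1%. Of the 21, 17 were higher in replicate 1 and 4 in replicate 2. With reads of annotated transcripts alone as the denominator, 9 transcripts in 5 genes were called, 5 of them among the 21. Of the shifts named here, those of Rcan1 and Smyd1 remained. Those of Txnl4a, Flot1, Rpl39 and Col4a2 could not be tested so, for want of a second annotated transcript or of 20 such reads in each library.

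Full annotated matches took the smallest share of reads in genes with the longest transcripts. Among reads of annotated and incomplete classes, full annotated matches made up 95.0% in replicate 1 and 95.5% in replicate 2 for genes whose longest annotated transcript with reads was 1 to 2 kb. The share was 83.0% and 83.2% at 4 to 6 kb, and 61.1% (60.7 to 61.5) and 59.6% (59.0 to 60.1) at 6 kb or longer. Under 1 kb it was 87.8% and 91.9%.

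Reads not assigned to annotated genes came mostly from single-exon models, and the most abundant loci described here lay opposite known genes. The most abundant such locus lay at chromosome 9, 77655847 to 77658186 on the minus strand, opposite exons of Klhl31, a kelch-family gene of muscle, with 1102 reads in replicate 1 and 2094 in replicate 2. A locus at chromosome 17, 39843013 to 39848035, opposite Gm26917 and Gm42418 and overlapping the annotated gene AY036118 and 1 further annotated gene on its own strand, had 1273 and 565 reads. A locus opposite Sept2 (chromosome 1, 93507713 to 93509733) had 331 and 350 reads. A locus at chromosome 7, 28187294 to 28189072, within the span of the kinase gene Dyrk1b on the other strand but almost wholly outside its exons, had 371 and 261. In all, 11682 loci were read, 2668 of them in both libraries, and single-exon models gave 88.0% of their reads.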

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

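Of the tests in this part, the full-match shares by length and the splice sites of the NIC class were chosen after the results they bear on were seen, and the length correction was added after seeing the data. The spike-in RNA, which no comparison of genes or transcripts used, has 1 known strand, and reads on the other strand numbered 231 in replicate 1 (0.858%, 0.755 to 0.975) and 162 in replicate 2 (1.03%, 0.886 to 1.20), above the 3 reads that a count of 0 allows.

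Antisense models such as the one opposite Klhl31 carried reads in both libraries, and a candidate explanation was sense RNA read on the wrong strand at the spike-in rate. At that rate most antisense reads would lie at loci where they are a small fraction of sense reads. Instead 65.8% of reads at antisense loci lay where the antisense share of all reads was over 10 times the spike-in antisense share. At loci at or under 3 times that share lay 17.5%. By locus, 33.8% of the 9760 were over 10 times. A locus with few reads passes that limit on 1 antisense read at any error rate, so these shares do not decide for small loci. Antisense reads were 93.9% and 96.9% of all reads at the Klhl31 locus in replicates 1 and 2, which argues against that explanation there. Strand errors that vary by transcript stay open, and no biological explanation was tested, since the series has 1 group.

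Genes with long transcripts had more reads in replicate 1, with a slope of 0.20 log2 units per doubling of length (SE 0.00672, 7490 genes). A difference confined to the genes of the fixed muscle and matrix lists is argued against by the slope outside them, 0.197 (SE 0.00680, 7359 genes). Inside them it was 0.29 (SE 0.0418, 131 genes). Muscle and matrix genes that are not listed fall outside, so wider programmes are not decided by this. For a difference in the capture or sequencing of long RNA the spike-in slope was 0.281 (SE 0.159, 26 spike-ins of 505 to 1994 nt), under 2 SE from 0, so this cannot be told apart, because the spike-ins are few and short. More shortened molecules in replicate 2 cannot be told apart at 4 to 6 kb, where the intervals of full matches overlap. They were 83.2% in replicate 2 (82.9 to 83.5) and 83.0% in replicate 1 (82.7 to 83.2). At 6 kb or longer full matches were 59.6% (59.0 to 60.1) and 61.1% (60.7 to 61.5), lower in replicate 2 as that explanation predicted. It stays open there, because gene counts include incomplete matches. A shortened molecule can still count for its gene, so these shares cannot decide why reads differed. The bins were split only after the pooled shares at 4 kb or longer, 75.5% in replicate 2 and 74.6% in replicate 1, were seen, and pooling decides nothing, since genes of 6 kb or longer gave 58046 of 151976 reads in replicate 1 and 30840 of 94517 in replicate 2, and a difference between the animals is untested.

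The class of 1 intron chain could differ between libraries: 923 of 8601 chains found in both as NIC or NNC had opposite classes, with 63.4% of their reads in replicate 1 and 56.3% in replicate 2. The main Atp2a1 model was NIC in replicate 1 and NNC in replicate 2, and the 21-exon model the other way round. A candidate explanation is that the class was set against models already registered in the library and not against GENCODE M21 alone. A splice site absent from GENCODE M21 lay in 64.7% of NIC reads in replicate 1 and 32.6% in replicate 2, but 91.8% and 71.5% of those reads belonged to the chains of opposite class, so the pattern itself largely fixed this value and the explanation cannot be told apart from others. Outside those chains the shares were 13.0% and 12.1%, computed after the others were seen, the tool's order of work was not analysed here, and no biological explanation was tested.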

How the results depend on the processing

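In this part, the length-bin correction and the recomputed classes were chosen after seeing the data. Calls of genes differing between the libraries numbered 207 and stayed between 157 and 224 under the scalings, minima of 5 and none, annotated reads, no genomic class and thinning, with 85 of the 170 calls from annotated reads shared. By direction annotated reads gave 134 and 36 in place of 144 and 63. All calls were 59 at a minimum of 100 reads, which tests fewer genes, 685 at any fold, where 49.1% were higher in replicate 1 in place of 69.6%, and 121 with the length correction, where the trend in length was removed. The coefficient of variation stayed between 0.177 and 0.184. Pearson's r was 0.911 with a pseudocount of 0.5 and 0.972 with 10, which weight genes near 0 differently. Transcripts with a different share numbered 9 with annotated reads as the denominator, 10 at 20 points, and 21 to 31 otherwise.

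Without the 10 most abundant genes, incomplete matches were 9.24% and unannotated spliced reads 11.1%, which leaves out Atp2a1. Recomputed classes gave NIC 4.12% and NNC 11.3%. Unannotated models were found in the other library for 64.7% and 75.9% at 2 or more reads, 99.5% and 100% at 10 or more, and 59.0% and 78.1% when 5 or more were required in both, for replicates 1 and 2. Over annotated reads alone, Atp2a1 held 4.22% of its pair, since its main models are unannotated, Chrne 77.9%, Myh4 39.7% of heavy-chain reads and the developmental chains 3.11%, and the cause was not tested for Chrne and the developmental chains. Annotated reads alone gave no value for Tnnt3 and Tnnt1. Of 19 other shares of paralogues and heavy chains, 10 moved by more than their SD over annotated reads, 8 up and 2 down. The length correction gave 99.798% for Atp2a1 in place of 99.788%. Genes of 6 kb or longer had 68.2% full matches when binned by their most abundant annotated transcript, a different set of genes.

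Leaving out a replicate gave 70.9% to 74.9% for annotated reads, 7.49% to 8.68% for incomplete matches, 13.9% to 16.9% for unannotated spliced, 5.89% to 12.1% for NIC and 4.75% to 8.01% for NNC. It gave 99.782% to 99.795% for Atp2a1, 78.0% to 81.0% for Tnnt3, 81.6% to 84.6% for Chrne, 60.9% to 68.6% for Myh4, 3.83% to 3.97% for the developmental chains, 87.8% to 91.9% for full matches under 1 kb and 59.6% to 61.1% at 6 kb or longer. Each such value rests on 1 library. Sums of 16 gene lists over annotated reads moved by more than the SD, 10 up and 6 down, and with other scalings none did. Depth limits calls: in simulation with counting noise 22 of 50 genes changed 2-fold passed the adjusted p.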

Other observations

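Imprinted, growth and other listed genes had these levels. The imprinted list summed to 6697 ± 459 CPM, and after H19 its highest members were the cell-cycle inhibitor Cdkn1c (2114 ± 123 CPM), Dlk1 and the hydrolase-family gene Mest (328 ± 29.7 CPM), with the growth factor Igf2 at 169.9 ± 4.47 CPM. Proliferation genes summed to 470.1 ± 26.6 CPM, and the tubulin gene Tubb5 gave 218 ± 23.4 CPM of this, while Rrm2, a subunit of ribonucleotide reductase, lay at 30.6 ± 1.20 CPM. Stress and immediate early genes summed to 143 ± 25.8 CPM, with the chaperone Hsp90aa1 at 35.8 ± 4.94 CPM and Jun at 23.3 ± 4.57 CPM. The 4 sex-label genes listed summed to 124 ± 22.6 CPM. Mitochondrially encoded genes summed to 535 ± 95.6 CPM, 0.0481% and 0.0603% of mouse reads, with mt-Co1 at 265 ± 70.5 CPM. Only assigned reads are listed, so whether mitochondrial reads were left out before counting is not shown. The mitochondrial values are thus not a measure of mitochondrial RNA level in the tissue. Keratinocyte genes summed to 6.96 ± 3.67 CPM, and to 0.708 CPM over annotated transcripts alone.

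Gapdh, a glycolytic enzyme gene, had 54.1 and 46.7 CPM in replicates 1 and 2, while Pgam2, another glycolytic enzyme gene, had 2092 and 2806 CPM, and both were named after their values were seen. The deposited tables list assigned reads alone, so they do not show whether reads of Gapdh were left out before counting, and its value is a count of assigned reads and not a measure of its RNA level. Spike-ins took 2.30% of reads in replicate 1 and 1.64% in replicate 2, with reads on 51 and 48 of the ERCC RNAs. Models with a single read made up 62.5% of the 92223 transcript models in replicate 1 and 61.4% of 73027 in replicate 2.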
